A study of Canis lupus familiaris with 14 samples.

How the data were processed

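Spatial transcriptomes of canine osteosarcoma, a bone tumour of dogs, were measured with 10x Visium version 1, a slide array on which each barcoded spot captures the RNA of the tissue lying over it. A spot can hold RNA from several cells, so no value here is a value of single cells. The labels give 14 fresh-frozen sections of 10 µm from 11 dogs. Each of the 11 dogs has 1 primary tumour section, dogs 1 and 2 each have 1 metastatic section, and dog 9 has 1 recurrent section. Same-numbered sections come from the same dog per the labels, so the dog number pairs sections of different lesion types. The organ that held each metastasis, the outcome of each dog and any batch or date are not given in the sources used here, and no comparison with survival was made.

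The deposited matrices hold UMI counts (unique molecular identifiers, counts of captured RNA molecules) per gene and spot, made with Space Ranger 2.1.0 per the file headers and the submitters' processing notes. The values were checked to be whole numbers of 1 or more, with no normalization. The number of spots in each matrix was checked against the number of spots that the deposited position table places over tissue, out of 4992 spots of the capture area. The genome build and the annotation are not given in the sources used here, so no coordinate is reported. The deposited gene table has 37952 features, of which 19373 carry a LOC name, and 37291 match a symbol of the RefSeq table used to check names. None of the names of the Mitochondrial encoded list was among the features.

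The 14 sections hold 20687 spots over tissue and 236.6 M UMIs. Totals per section run from 7.50 to 33.3 M UMIs, with a mean of 15.9 ± 8.46 M in the primaries (SD, n = 11). Levels of single genes are CPM on TMM-scaled section totals, and levels of lists are CPM on the unscaled section totals. Intervals on single-section values are exact Poisson intervals and cover counting error only.

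Before the data were examined, 21 cell type lists and 9 pathway lists were written down, together with the comparisons, the tests, the alternatives and the rule for genes to be named. No gene is shared between the lists used in the co-localisation test. The Sympathetic neuron list was added after neuronal genes had been seen among the called genes. Cell types are named only through these marker lists. No deconvolution and no cell-doublet call was run.

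For the metastatic against the primary sections, counts were summed per section over all tissue spots, so that the section and not the spot was the replicate. edgeR 4.0.16 (TMM scaling, its expression filter by group, quasi-likelihood F test, Benjamini-Hochberg 0.05) was fitted to all 14 sections with 1 coefficient per lesion type. Lists with at least 5 tested members were tested with camera of limma 3.58.1 at its preset correlation and again with an estimated correlation. A fit with the dog as a block has 1 residual degree of freedom, against 11 without it, and the consensus correlation within a dog was 0.108. For that reason the fit without a block was the one reported and the blocked fit an alternative. The recurrent and the primary section of dog 9 are 1 library each. They were compared without a test, as log2 ratios of TMM-scaled counts per M (CPM) with a prior count of 2, beside the range of the 11 primaries. Each list's median ratio was placed among 10000 random lists matched on size and mean expression.

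For T-cell-rich and osteoclast-rich spots, spots under 500 UMIs were left out. A spot's score was the UMIs of the list over all UMIs, both summed over the spot and its up to 6 adjacent tissue spots. The top 10% of spots of each section formed the rich class. Counts were summed per section and class, and edgeR was fitted over the 11 primaries with the section as a block. Genes of the list that chose the spots were left out of the counts of called genes. The interaction of spot class and lesion type was tested in the same way over 11 primaries and 2 metastases. Co-localisation was the Spearman correlation across spots of 2 list scores, partial on the spot's UMI total. It was tested over sections with an exact two-sided sign-flip permutation test of the mean Fisher z and Benjamini-Hochberg adjustment over 136 pairs. The smallest p this test can give over 11 sections is 0.000977. Moran's I, a measure of how alike adjacent spots are, was computed on log1p of UMIs per 10000 for genes with a UMI in at least 5% of the spots of every primary. T cell list levels were related to 28 other lists across the primaries with Pearson's r and Spearman's rho, each with a two-sided permutation test of 100000 resamples and Benjamini-Hochberg adjustment.

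Named genes of the metastatic comparison were the 10 highest and 10 lowest by log2 fold change among called genes whose difference within dog 1 and within dog 2 had the sign of the fold, plus up to 4 called members of each list by smallest p. For spot classes they were the 10 highest and 10 lowest among called genes with the same sign in at least 10 of 11 sections, plus up to 4 called members per list. For the interaction they were up to 5 by smallest p in each direction. For dog 9 they were the 10 highest and 10 lowest log2 ratios among genes of at least 50 CPM in either library whose recurrent value lay outside the range of all primaries. For Moran's I they were the 20 genes with the highest mean. Members of a list that did not pass are given only as values, and names that are only LOC identifiers were not used. Genes of the major histocompatibility complex have near-identical copies, so their counts are uncertain.

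The model fits and the sign-flip test were tested on simulated data. In simulated counts with the dispersion of these sections, the metastatic comparison called 0% of genes changed by 1 on the log2 scale, 6.06% of those changed by 2 and 40.9% of those changed by 4, and 0.00572% of unchanged genes. The spot class comparisons called 95.6% (T-cell-rich) and 94.1% (osteoclast-rich) of genes changed by 1. They called 0.231% and 0.161% of unchanged genes. The sign-flip test called 96.1% of simulated correlated pairs, with a mean Fisher z of 0.1 and an SD of 0.05 between sections. It called 0.393% of unrelated pairs. The first share holds for that spread only.

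Alternatives were RLE scaling, no expression filter, DESeq2 1.42.0, the dog as a fixed block or as a random block in limma-voom, the primaries of dogs 1 and 2 left out, the recurrent section left out, other minimum UMIs, spots thinned to 1000 UMIs, other shares of spots, scores without neighbours, no section block, and each section left out in turn. Scores summed over neighbours, plain correlations and another list score were tried where they applied. Alternatives chosen after seeing the data are named in the closing section. Image scale factors were not used and tissue images were not analysed here. Work was done in R 4.3.3 and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.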

Results

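Gene expression was mapped in 14 sections of canine osteosarcoma, a bone-forming tumour of dogs, with barcoded spots that each collect RNA from a small patch of tissue. The sections fall into 11 primary tumours from 11 dogs, 2 metastatic lesions from dogs 1 and 2, and 1 recurrent lesion from dog 9. Together they hold 20687 spots. Section totals were 15.9 ± 8.46 M UMIs in the primaries (SD, n = 11), 20.2 and 18.8 M in the metastatic sections of dogs 1 and 2, and 23.1 M in the recurrent section. The lowest total was 7.50 M (primary of dog 11) and the highest 33.3 M (primary of dog 5). Median UMIs per spot ran from 4524 in the primary of dog 6 to 16778.5 in the primary of dog 8. In the primary of dog 4, 184 of 1039 spots (17.7%) had fewer than 500 UMIs. Because a spot can cover several cells, the levels below are levels of tissue patches and sections, and cell types are named only through marker lists.

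The first comparison asked how the metastatic sections differ from primary tumours. Both metastatic sections carried RNA of marker genes of tissues other than bone, and the markers differed between the dogs. Such RNA was not confined to metastatic sections. In the primary of dog 1, UMIs of the Skeletal muscle list were gathered in part of the section (Moran's I 0.835). In the metastatic section of dog 1, the Lung epithelium list reached 321 CPM, against 0.371 to 12.5 CPM in the 11 primaries. SCGB1A1, the club cell secretory protein, stood at 176 CPM there and at 0.234 CPM in the metastatic section of dog 2. SFTPC, surfactant protein C of alveolar type 2 cells, stood at 86.6 and 2.81 CPM and had 1 count in all primaries together (edgeR adjusted p = 6.63e-06). The metastatic section of dog 2 carried other markers, among them the adipocyte fatty acid binding protein FABP4 at 1042 CPM and the mast cell chymase CMA1 at 155 CPM. It also carried the neuropeptide galanin (GAL) at 1265 CPM, the neurofilament NEFL at 316 CPM and the neuronal growth protein STMN2 at 633 CPM. In the primaries these 3 neuronal genes averaged 0.188 ± 0.231, 0.0416 ± 0.0774 and 0.187 ± 0.346 CPM (SD, n = 11).

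Of 18474 genes tested over 11 primary and 2 metastatic sections, 205 were higher and 1 lower in the metastatic sections, in a fit that also held the recurrent section. Without the recurrent section 64 were higher and 1 lower, of 16525 genes. The expression filter goes by the smallest group, which is 1 section with the recurrent section and 2 without it. Genes with enough counts in 1 section only could thus enter the fit with it and not the fit without it. Of the named genes tested without it, 15 stayed called and 3 did not. How much of the drop came from the filter was not tested. Fitted log2 fold changes of the highest named genes were 11.72 ± 1.35 (SE) for GAL, 11.52 ± 1.23 for NEFL, 10.66 ± 1.30 for STMN2, 9.33 ± 1.11 for the vesicular monoamine transporter SLC18A1, 8.44 ± 1.10 for the secretory granule protein CHGB and 8.16 ± 1.25 for SCGB1A1. These folds came from 1 dog or the other: without the metastatic section of dog 2 they were −0.90 for GAL, −1.15 for CHGB and 1.97 for STMN2, with NEFL and SLC18A1 not tested, and without that of dog 1 the fold was −0.30 for SCGB1A1. The complement component C6 stood at 7.23 and 58.9 CPM in the metastatic sections of dogs 1 and 2, against at most 0.263 CPM in any primary. The membrane protein FXYD3 stood at 6.79 and 1.05 CPM, with 1 count in all primaries together. The gene called lower was CDH15, the M-cadherin of muscle precursor cells, at 1.38 and 0.820 CPM in the metastatic sections and 87.4 ± 61.7 CPM in the primaries (13.9 to 202 CPM, log2 change −6.30 ± 1.20, adjusted p = 0.0166). It was not called without the metastatic section of dog 1 or of dog 2 (log2 change −6.72, adjusted p = 0.0861, and −6.01, adjusted p = 1.00), with the dog as a block (−6.24, 0.917) or in limma-voom (−5.97, 0.129), so the fold stayed while the call was lost. Of the 205 higher genes, 195 lay above every primary in the metastatic section of dog 2 and 45 in that of dog 1, and 35 did so in both. In 170 of them the section of dog 2 was 10 times or more above that of dog 1, and in 11 the reverse held. The calls rested on single sections, since 7 genes were called higher without the metastatic section of dog 2 and 321 without that of dog 1. SFTPC and FXYD3 were called higher in both of those fits, each of which has 1 metastatic section, assumed to vary as sections of the other groups do. Without the primary of dog 5, 135 genes were higher and 2 lower.

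**Figure D1:**
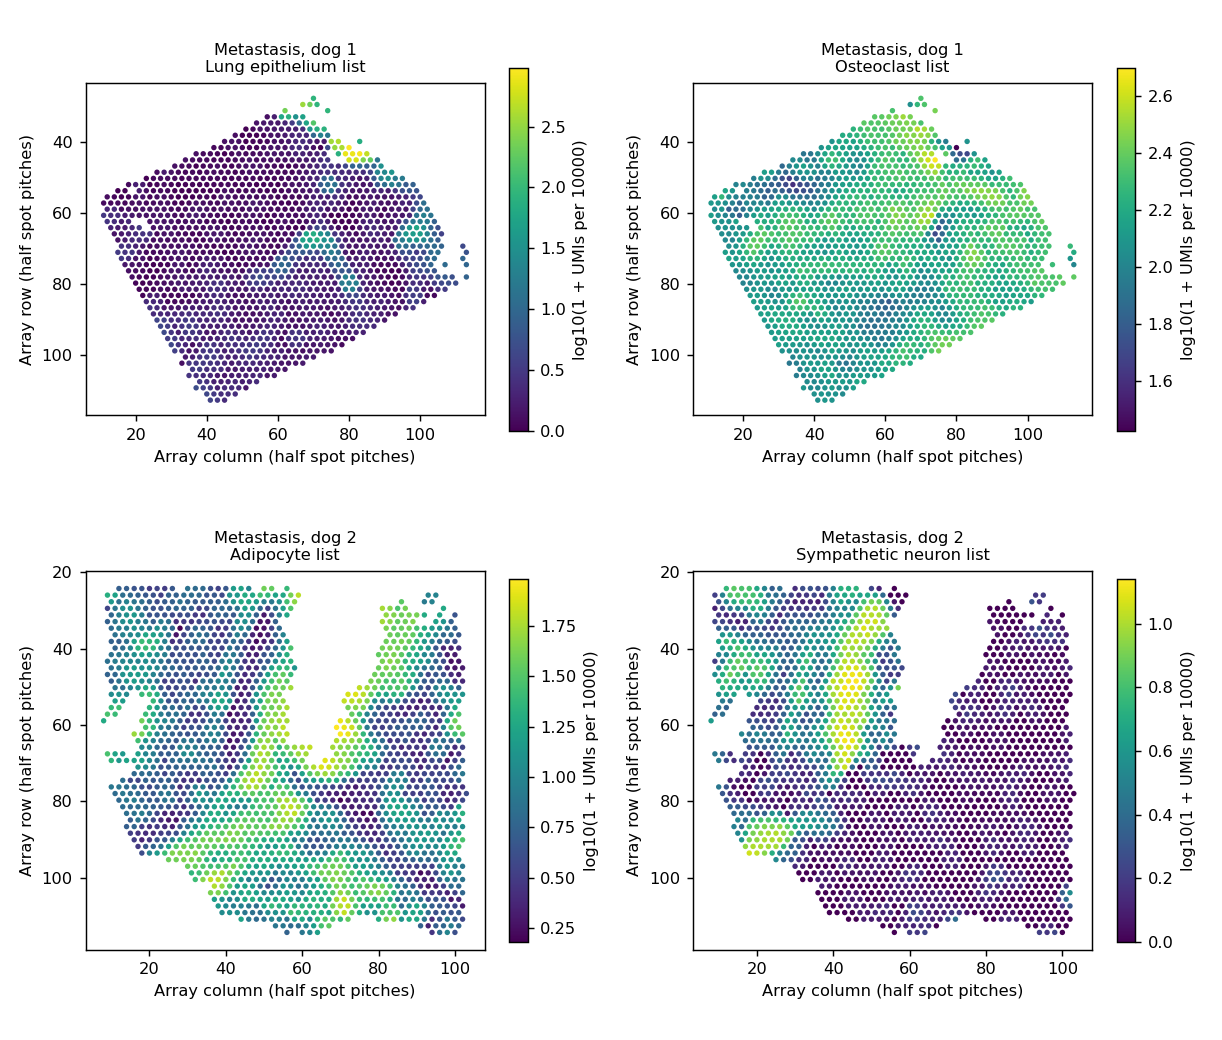
Maps of the 2 metastatic sections, with each tissue spot placed at its array column and row, in units of 0.5 of the spot pitch and to scale. Colour gives log10(1 + UMIs per 10000) of a gene list over the spot and its neighbours, each map on its own scale. The top maps show the Lung epithelium and Osteoclast lists in dog 1 and the bottom maps the Adipocyte and Sympathetic neuron lists in dog 2. Lung epithelium UMIs were gathered in part of the section, with 83.0% of them in the top 10% of spots.

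By gene list, 14 of 27 lists were higher and 4 lower in the metastatic sections with camera at its preset correlation, and 0 passed in either direction with an estimated correlation (lowest adjusted p = 0.0579; unadjusted p under 0.05 in 7 lists higher and 2 lower). At the preset correlation, 9 lists were higher and 5 lower without the metastatic section of dog 2, and 10 and 2 without that of dog 1. With the dog as a block (1 residual degree of freedom), 13 were higher and 5 lower, of which 11 and 4 were shared. The Fibroblast list then leaned lower without passing (adjusted p = 0.597), the Chemokine and Interferon response lists no longer passed (0.0725 each), and the Cytotoxic and Neutrophil lists (higher, 0.000144 and 0.00940) and the Skeletal muscle list (lower, 0.000167) did. The block was fitted at the preset correlation only, and with an estimated correlation and no block the last 3 had adjusted p of 0.561, 0.358 and 0.703. In the Lung epithelium list 3 of 7 tested members passed over all genes and 6 adjusted over the list alone. For the Adipocyte list these counts were 3 and 6 of 7, for the Mast cell list 3 and 6 of 6, for the Schwann cell list 2 and 5 of 7, and for the Epithelium list 2 and 4 of 10. Adjusted p with an estimated correlation was 0.0579, 0.135, 0.137, 0.196 and 0.0579 for these 5 lists. At the preset correlation the Lung epithelium list did not pass without the metastatic section of dog 1 (0.0695). Without that of dog 2 the Adipocyte list leaned lower (0.336) and the Mast cell and Schwann cell lists were not tested. In the Fibroblast list, 3 of 14 members passed over all genes and 4 adjusted over the list alone, among them CLEC3B (log2 change 9.27 ± 1.41), CFD (5.39 ± 1.06) and C7 (5.44 ± 1.21). The list's adjusted p was 0.00193, and 0.240 with an estimated correlation, and it leaned lower without the metastatic section of dog 2 (0.823). Adipocytes also express CFD, which stood at 8221 CPM in the metastatic section of dog 2 and 159 CPM in that of dog 1.

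Several immune lists, named below, stood higher in the metastatic sections at the preset correlation, while the Neutrophil, Cytotoxic and Dendritic cell lists did not pass (adjusted p = 0.0844, 0.0928 and 0.128). No single immune member passed over all genes apart from the mast cell genes and the chemokine CCL19 (log2 change 5.51 ± 1.16, adjusted p = 0.0298). All 19 tested members of the Macrophage list had positive log2 changes, with a median of 1.54, and 2 passed adjusted over the list alone. The list summed to 5740 and 10601 CPM in the metastatic sections of dogs 1 and 2 and to 547 to 4300 CPM in the primaries (adjusted p = 1.11e-14, and 0.0666 with an estimated correlation). APOE, an apolipoprotein not confined to macrophages, stood at 2114 and 7510 CPM against 599 ± 435 CPM in the primaries and did not pass (edgeR adjusted p = 0.0852). Its level is large beside the sums of the Macrophage list, so these sums need not reflect macrophages alone. Positive members numbered 14 of 15 in the Antigen presentation list (median log2 change 1.36), 14 of 17 in the T cell list (1.05), 8 of 10 in the Plasma cell list (1.03), 11 of 11 in the Immune checkpoint list (1.16), 7 of 8 in the Chemokine list (1.39), 9 of 9 in the B cell list (0.53) and 14 of 18 in the Interferon response list (0.55). Adjusted p with an estimated correlation was 0.164, 0.262, 0.0666, 0.148, 0.250, 0.250 and 0.491 in the same order. Several of these calls rested on 1 section at the preset correlation. Without the metastatic section of dog 1 the T cell (0.191), Plasma cell (0.191), Immune checkpoint (0.366), Interferon response (0.265) and B cell (0.0695) lists no longer passed. Without that of dog 2 the B cell list did not pass (0.175) and the Chemokine list leaned lower (0.823). The Macrophage and Antigen presentation lists passed in both fits.

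The lists that stood lower were those of bone formation, cartilage, proliferation and hypoxia, of which the Cartilage (0.191) and Hypoxia and glycolysis (0.104) lists did not pass without the metastatic section of dog 1. In the Osteoblast list, 13 of 14 members had negative log2 changes (median −4.15), 0 passed over all genes in edgeR and 3 passed adjusted over the list alone. The bone matrix gene IBSP stood at 9.74 and 2.17 CPM in the metastatic sections and at 30.1 to 10428 CPM in the primaries (adjusted p = 0.306). In dog 2 the list summed to 508 CPM in the metastatic section and 40210 CPM in the primary. All 20 members of the Cell cycle list had negative log2 changes (median −1.31), with 0 members passing over all genes or over the list alone. The list summed to 175 CPM in the metastatic section of dog 2, below every other section, and to 735 CPM in that of dog 1, inside the primaries' range of 482 to 2385 CPM. Medians were −0.84 for the Hypoxia and glycolysis list and −4.17 for the Cartilage list. Adjusted p with an estimated correlation was 0.137, 0.139, 0.196 and 0.456 for the Osteoblast, Cell cycle, Hypoxia and glycolysis and Cartilage lists. With the dog as a block, 0 genes were called in edgeR in either direction (unadjusted p under 0.05 in 320 higher and 217 lower genes, 1 residual degree of freedom). limma-voom with the dog as a random block called 34 higher and 0 lower, and DESeq2 without a block called 233 and 56.

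**Figure D2:**
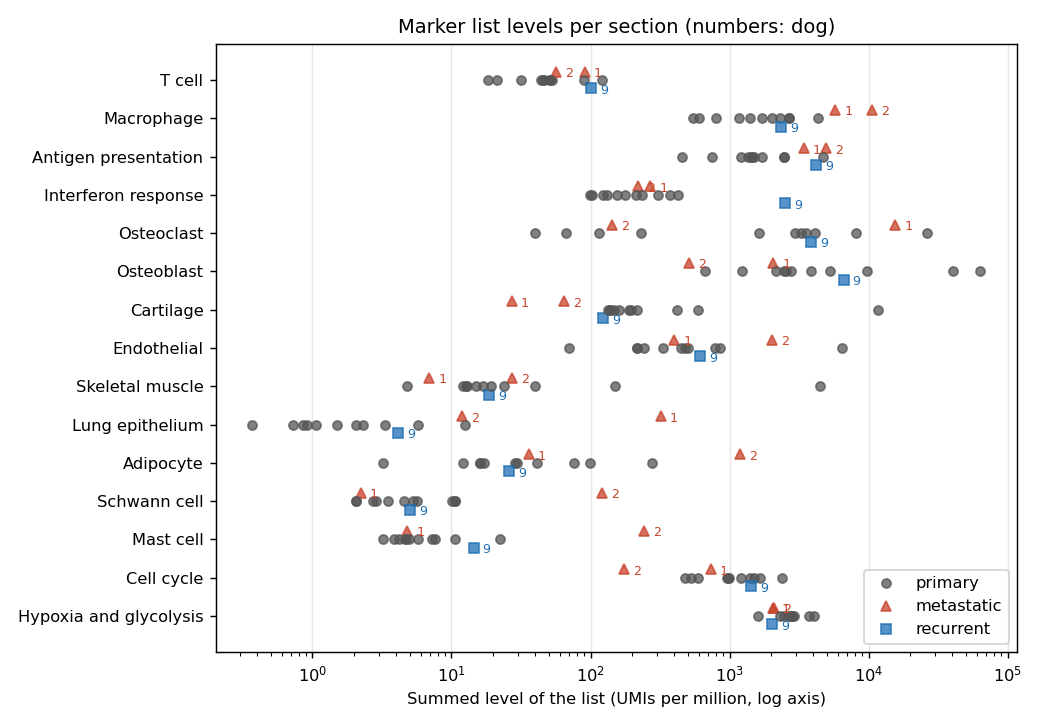
Summed level of selected gene lists in each section, in CPM on a logarithmic axis, with 1 point per section and the lesion types told apart by marker. The Lung epithelium list of the metastatic section of dog 1 (321 CPM), the Adipocyte list of the metastatic section of dog 2 (1194 CPM) and the Interferon response list of the recurrent section (2521 CPM) lie above all primaries.

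The recurrent section was set beside the primary section of the same dog. Genes induced by interferon were the group that stood furthest from the primaries. All 18 members of the Interferon response list were higher in the recurrent section than in the primary of dog 9 and above all 11 primaries, in 17 of them by more than the 95% Poisson interval of the recurrent value. The list summed to 2521 CPM, against 425 CPM in the primary of dog 9, the highest primary. ISG15, a ubiquitin-like protein, stood at 855 and 93.7 CPM, the antiviral GTPase MX1 at 365 CPM (log2 ratio 4.92), and OAS2 at 199 and 49.1 CPM. The list's median log2 ratio was 3.08, above all 10000 random lists. Ratios were also ranked among the genes of at least 50 CPM in either section of dog 9 whose recurrent value lay outside all primaries. The 10 highest included the list members IFIT2 (52.8 and 1.39 CPM) and CMPK2 (59.2 and 1.65 CPM), and ZBP1 (67.6 and 0.0867 CPM) and XAF1 (51.8 and 0.607 CPM), which are interferon-induced and not in the list.

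**Figure D3:**
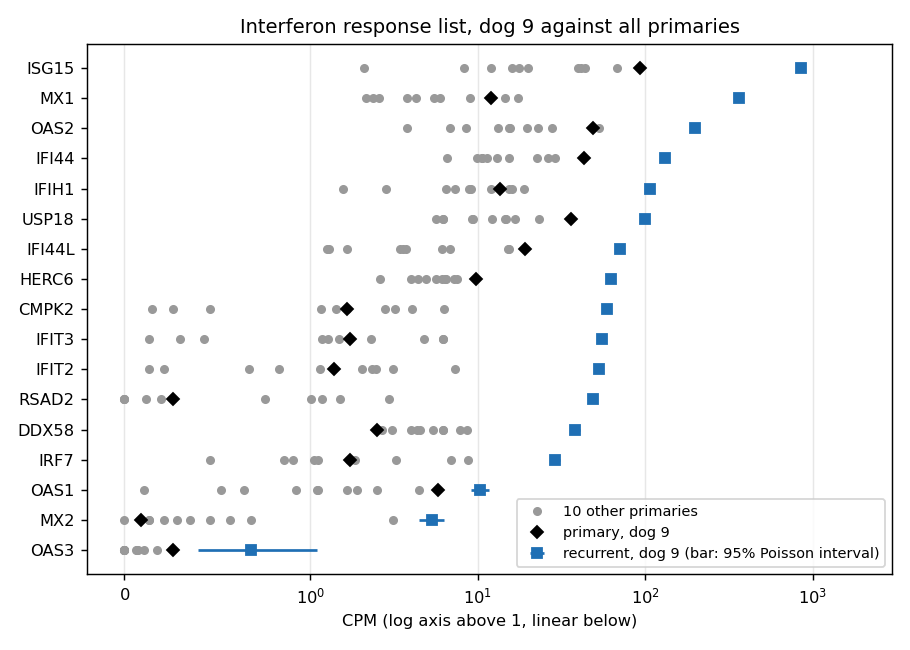
Level in CPM (axis logarithmic above 1 and linear below) of the 17 members of the Interferon response list whose recurrent interval lies above every primary. Grey points are the 10 other primaries, the diamond is the primary of dog 9, and the square with a bar is the recurrent section with its 95% Poisson interval, which covers counting error only. The squares lie between 0.683 CPM (OAS3) and 855 CPM (ISG15).

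The highest ratio in that ranking was that of WIF1, a secreted inhibitor of Wnt signalling, at 6703 CPM in the recurrent section, 2.95 CPM in the primary of dog 9 and at most 1404 CPM in any primary (log2 ratio 11.09). T cell markers were also higher, in 15 of 17 members (median log2 ratio 3.01), of which 4 of 17 lay above all primaries. IL7R stood at 13.6 CPM (95% Poisson interval 12.2 to 15.1) against 0.0867 CPM (0.00219 to 0.483), while CD8B (3.70 and 7.72 CPM) and CD247 (7.84 and 17.4 CPM) were lower. Antigen presentation genes were higher in 14 of 15 members (median 1.54) and above all primaries in 5, with B2M at 432 and 49.0 CPM and the immunoproteasome gene PSMB8 at 147 and 9.36 CPM. Medians of the Macrophage, Osteoblast and Fibroblast lists were 1.91, 1.63 and 1.47, each above all random lists, but 0 of their 19, 14 and 14 members lay above all primaries, so these levels lie inside the range of primary tumours. The Hypoxia and glycolysis list had 2 of 18 members higher, 3 below all primaries and a median below all random lists, and the Cartilage list had a median of −1.13 with 0 members below all primaries. GDF1, a growth factor of the TGF-beta family, had the lowest ratio among named genes (1.00 and 61.5 CPM, log2 ratio −5.77), and the amyloid precursor gene APP stood at 157 and 1255 CPM. These are differences between 1 section and 1 section, so no test was made. Among genes of at least 50 CPM in either section, 185 were above and 55 below both the primary of dog 9 and all other primaries.

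The next comparison asked what else is expressed in the spots of each primary tumour that score highest for T cell markers. The class is relative to its section. Its share of T cell list UMIs was 2.26 (dog 8) to 6.93 (dog 11) times that of other spots. The list was scarce, at 18.3 to 121 CPM per section. Its Moran's I was 0.325 in dog 5 and only 0.0181 to 0.118 in the other primaries. The rich spots thus need not be T cell aggregates, and the part of counting noise in their choice was not tested. T-cell-rich spots had more macrophage and antigen presentation RNA and less of proliferation and hypoxia genes by camera at its preset correlation. None of these 4 list calls passed with an estimated correlation (adjusted p = 0.116, 0.116, 0.0536 and 0.116). The chemokine CCL5, which T and natural killer cells secrete, was 1.30 ± 0.18 (SE) higher on the log2 scale (134 against 45.2 CPM, 9 of 11 sections, adjusted p = 0.000463). All 16 tested members of the Macrophage list had positive log2 changes (median 0.55), with 0 passing over all genes in edgeR and 15 passing adjusted over the list alone. All 13 members of the Antigen presentation list were positive (median 0.53, 9 passing over the list alone), as were all 11 of the Interferon response list (0.43, 2 over the list alone) and all 10 of the Endothelial list (0.27, 0 over the list alone). CD74, the invariant chain of class II presentation, stood at 998 against 487 CPM and was higher in 10 of 11 sections, without passing (adjusted p = 0.0629).

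In the Cell cycle list 19 of 20 members had negative changes (median −0.17), 1 fell over all genes and 7 adjusted over the list alone. That gene was BIRC5, an inhibitor of apoptosis expressed in dividing cells, which fell by 0.31 on the log2 scale in 11 of 11 sections. The condensin gene NCAPH fell by 0.51 in 10 of 11. In the Hypoxia and glycolysis list 14 of 17 members were negative (median −0.22), 1 fell over all genes and 9 over the list alone. The glucose transporter SLC2A1 fell by 0.34 in 11 of 11 sections, and DDIT4, a gene induced by hypoxia and stress, fell by 0.40 in 10 of 11. The serine synthesis enzyme PSAT1 (−0.51), the ribonuclease RNASEH1 (−0.38), the mitochondrial RNA-binding protein SLIRP (−0.31) and the respiratory chain subunit NDUFS4 (−0.27) also fell. RASSF2 (0.87 ± 0.18, 11 of 11 sections) and BPI, a bactericidal protein (0.64 ± 0.14, 10 of 11), rose. The camera calls of the Interferon response, Endothelial, Osteoblast and Mural lists were also lost with an estimated correlation, where adjusted p was 0.163, 0.163, 0.300 and 0.163. Over 11649 genes, 19 were higher and 10 lower with TMM scaling, and 30 and 1 with RLE scaling. T-cell-rich spots had lower UMI totals in all 11 primaries. Once every spot was thinned to 1000 UMIs, 4 genes were called higher and 0 lower in edgeR (unadjusted p under 0.05 in 292 lower genes). The changes of RNASEH1 and SLC2A1 then turned positive. Without the primary of dog 7 the counts were 8 higher and 37 lower, and without that of dog 8 they were 32 and 13. The higher genes numbered 11, 9, 10 and 11 without the primaries of dogs 2, 9, 10 and 11, and the lower genes 5, 2, 5, 3, 2, 4, 4 and 4 without those of dogs 1, 2, 3, 4, 6, 9, 10 and 11.

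Osteoclast-rich spots, chosen by markers of the cells that resorb bone, differed from other spots in many more genes. The class is relative to its section. The list was scarce in dogs 4, 11 and 3 (39.9, 67.2 and 115 CPM, against 229 CPM or more elsewhere). Their rich spots held a smaller share of its UMIs than the other spots of dogs 1, 2, 6, 7, 8, 9 and 10. The list was not gathered in dogs 4 and 11 (Moran's I −0.00512 and 0.00673). Section counts below include these sections. The collagenase MMP1 was 1.69 ± 0.19 (SE) higher on the log2 scale (10 of 11 sections), the sodium/proton exchanger SLC9B2 1.45 ± 0.18, the lysosomal glycoprotein CD68 1.40 ± 0.14 (11 of 11), carbonic anhydrase CA2 1.39 ± 0.21 and SNX10, a sorting nexin needed for bone resorption, 1.23 ± 0.15. DPP4 (1.48), EMB (1.43), CD84 (1.43), MATK (1.27) and LAT2 (1.22) completed the 10 highest. In the Macrophage list 9 of 16 members had positive changes (median 0.04) and 5 passed, all higher, including CSF1R (0.73), CD14 (0.73) and LAPTM5 (0.67). In the Matrix list 3 of 21 fell over all genes and 6 over the list alone, with COL1A2 at −0.38, SPARC at −0.27 and the collagen chaperone SERPINH1 at −0.24. In the Osteoblast list 3 of 13 tested members had positive changes (median −0.26), and 2 rose and 7 fell adjusted over the list alone. MMP13 (0.96) and SPP1 (1.34, 8 of 11 sections) rose, while IFITM5 (−0.85) and TNFRSF11B, which encodes the osteoclast inhibitor osteoprotegerin (−0.73), fell. IGFBP2, an insulin-like growth factor binding protein, also fell (−0.74 ± 0.20). B2M (0.49, 11 of 11) and PLVAP of fenestrated endothelium (0.44) rose and the collagen hydroxylase P4HA1 fell (−0.41). Over 11588 genes, 224 were higher and 194 lower with TMM scaling, and 265 and 68 with RLE scaling. The 5 lists that camera called (Macrophage, Interferon response and Endothelial higher, Matrix and Osteoblast lower) had an adjusted p of 0.612 with an estimated correlation. Without the primary of dog 2, 145 genes were higher and 78 lower. The lower genes numbered 72 without the primary of dog 9, 100 without that of dog 10, 106 without that of dog 1, 114 without that of dog 6 and 128 without that of dog 11.

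Whether the T-cell-rich effect differed between lesion types was tested as an interaction over 11 primaries and 2 metastases. Of 11700 genes, 0 had a higher and 5 a lower effect in metastases in edgeR (unadjusted p under 0.05 in 618 and 487). The 5 were SYT11, L1CAM, VAT1L, CEP120 and NCAM1, among which L1CAM and NCAM1 are cell adhesion molecules of the nervous system. L1CAM was 0.38 higher on the log2 scale in T-cell-rich spots of primaries, with changes of −3.01 and −2.07 in the metastatic sections of dogs 1 and 2. Without the metastatic section of dog 1, 63 genes had a lower effect, and without that of dog 2, 46 had a higher and 2 a lower effect.

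Across spots of the primaries, 15 of 136 pairs of lists were correlated beyond the spread between dogs, 14 positively and 1 negatively. The strongest was that of the Macrophage and Antigen presentation lists, with a mean partial rho of 0.492 (11 of 11 sections). Antigen presentation also went with the Endothelial (0.203), Cytotoxic (0.183), Interferon response (0.152) and T cell (0.124) lists, each in 11 of 11 sections. T cell scores went with Cytotoxic (0.119, 10 of 11) and Macrophage scores (0.114, 11 of 11), and Cartilage with Fibroblast scores (0.142, 11 of 11). The adjusted exact permutation p of the pairs positive in 11 of 11 sections was 0.0133. The negative pair was Endothelial with Hypoxia and glycolysis (−0.170, adjusted exact permutation p = 0.0354), and 0 negative pairs passed without any 1 of the primaries of dogs 1, 2, 4, 5, 6, 7, 9 or 11, against 2 without that of dog 3 or 8. Random lists of matched expression had a median rho of 0.00487, with 95% between −0.0762 and 0.0865. With spots thinned to 1000 UMIs, 0 pairs passed the sign-flip test (unadjusted p under 0.05 in 27 pairs).

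**Figure D4:**
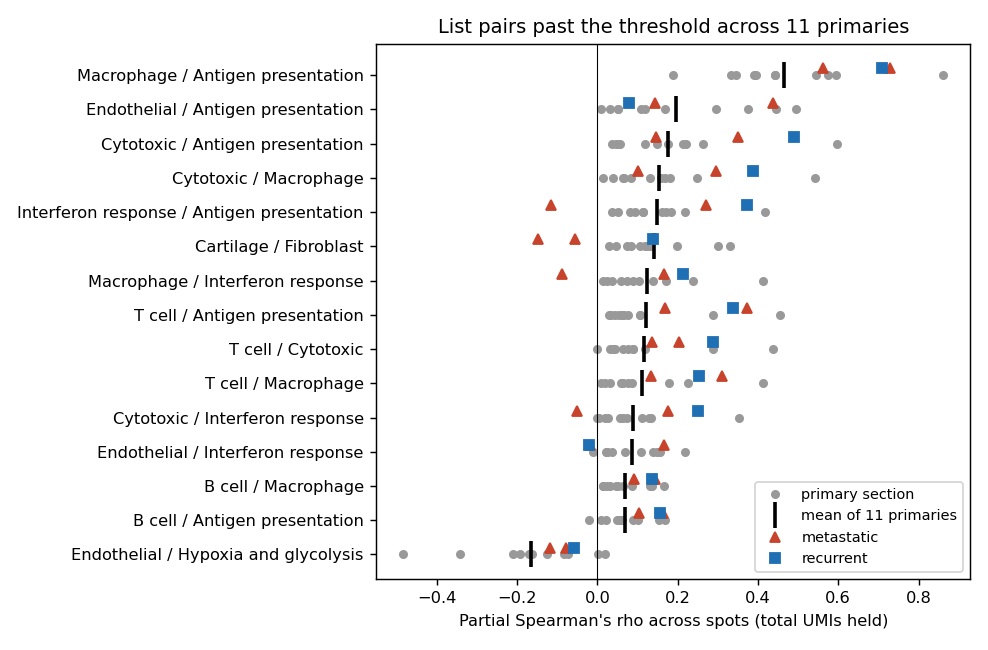
Partial Spearman rho across spots for the 15 list pairs past the threshold, with 1 point per primary section (n = 11) and a bar at the arithmetic mean over sections. The Macrophage and Antigen presentation pair has the highest mean, and the Endothelial and Hypoxia and glycolysis pair is the one with a negative mean.

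Across the 11 primaries, sections with more T cell RNA had more macrophage RNA. The T cell list level went with that of the Macrophage list (Pearson r = 0.851, adjusted permutation p = 0.028; Spearman rho = 0.709, adjusted p = 0.168) and of the Antigen presentation list (r = 0.807, adjusted p = 0.0371; rho = 0.845, adjusted p = 0.0484). It also went with the B cell list (r = 0.755, adjusted p = 0.0463; rho = 0.645, adjusted p = 0.257) and against the Cartilage list (r = −0.725, adjusted p = 0.0371; rho = −0.536, adjusted p = 0.437). Raw permutation p of Pearson's r was 0.0010, 0.0040, 0.0066 and 0.0036 in that order, and 28 relations were computed. Without the primaries of dogs 7 and 11, which lay farthest from the median T cell level, r was 0.690, 0.458, 0.557 and −0.703 in that order, and 0 of 28 relations passed the permutation test after adjustment (unadjusted p under 0.05 in 2, Macrophage at 0.0365 and Cartilage at 0.0349). With the mean over members of log2 (CPM + 1) as the level, 7 relations passed, which left out 2 of these 4: B cell (adjusted p = 0.0832) and Cartilage (r = −0.342, adjusted p = 0.410). No batch is given in the sources used here, so no value within batches could be computed.

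Spatial patterning was measured gene by gene. Of 7089 genes, the highest Moran's I in the primaries belonged to the actin-binding TMSB10 (0.519 ± 0.160, SD, n = 11), the collagen genes COL1A2 (0.5002 ± 0.1927) and COL1A1 (0.430 ± 0.153) and the matrix protein SPARC (0.412 ± 0.197). COL3A1 (0.394 ± 0.174), the osteoclast phosphatase ACP5 (0.370 ± 0.235) and the bone genes IBSP (0.345 ± 0.193) and BGLAP (0.336 ± 0.240) were also among the 20 highest. The other 12 were VIM, S100A6, FTL, ACTB and 8 ribosomal protein genes. By list, the Matrix list had the highest value (0.514 ± 0.180), and the T cell list a low one (0.0787 ± 0.0869). With spots thinned to 1000 UMIs, 16 of the 20 highest genes, counted with or without a usable name, remained among the 20 highest. The named genes take in RPS4X, of rank 21, which stood at rank 50 with thinning.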

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

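The tests of other tissue, of depth, of UMI totals, of section edges and of regrouped spot classes were chosen after the results they measure had been seen. The tests on UMI totals and on section edges were first run on the called genes that passed the expression filter, and were then extended to all 29 called genes. The test of immune RNA in the recurrent section was also chosen after the data were seen. It replaced a test on spots without an immune UMI, set beforehand and dropped since the 8 such recurrent spots hold 5201 UMIs in all and are shallow.

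For 5 genes the difference between T-cell-rich and other spots differed between metastatic and primary sections by a test of the interaction. The difference of log2 changes, metastatic minus primary, was −2.02 for SYT11 (adjusted p = 0.00517), −2.37 for L1CAM (0.0105), −2.50 for VAT1L (0.0221), −1.61 for CEP120 (0.0221) and −1.37 for NCAM1 (0.0221). In both metastatic sections the 5 genes were lower in T-cell-rich spots, with log2 changes from −1.11 (NCAM1 in dog 1) to −3.01 (L1CAM in dog 1), against −0.16 to 0.38 in the primaries. VAT1L was itself low in the metastatic section of dog 1 (log2 change −5.45 from the primaries). Its change between spots there may thus rest on few counts. Neuronal RNA was gathered in parts of the metastatic section of dog 2, and whether it accounts for these differences was not tested. All 5 were called again without the metastatic section of dog 1 and 0 of them without that of dog 2, where the differences were −1.95 for SYT11, −6.76 for L1CAM, −4.34 for VAT1L, −1.44 for CEP120 and −0.91 for NCAM1. Each of those fits has 1 metastatic section, assumed to vary as sections of the other groups do.

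The 205 genes higher in metastatic sections were weighed against depth and other tissue. Unusual section totals are argued against, since those of the metastatic sections, 18.8 and 20.2 M UMIs, lie inside the range of the primaries (7.50 to 33.3 M). With spots thinned to at most 1000 UMIs 98 genes were called higher, 88 of the 205 among them. The count of calls thus depended on depth. RNA from other tissue in the sections stays open as a candidate explanation. In the metastatic section of dog 2, 140 of 183 called genes outside the lists used (76.5%) were higher in other-tissue spots than elsewhere. These spots had 20 or more other-tissue UMIs per 10000, and random gene sets of matched expression gave 54.1% to 68.3%. In the metastatic section of dog 1, 65 of 75 such genes (86.7%) were higher in its 63 other-tissue spots. Random gene sets gave 62.7% to 81.3% there. That test is partly circular. The Sympathetic neuron list, which helped choose the spots, was added after neuronal genes were seen among the called genes. Leaving out spots with 5 or more such UMIs gave 9 genes, against 39 to 138 with as many random spots left out. That limit kept 26 of 1933 spots and 0.118 M UMIs in the metastatic section of dog 2, and the random draws were not matched on UMIs. It also left out 745 of 1268 spots of the primary of dog 1, against 175 of 1466 in the metastatic section of dog 1. Random spots alone took the count from 205 to a median of 57.5, below the bound of more than 1/2 set for the test. Leaving out spots with 20 or more (921 of 1933) gave 149 genes, 134 of the 205 among them. Since 1907 of 1933 spots had 5 or more, most spots kept still held other-tissue RNA, so these calls cannot decide. GAL changed by 10.83 at the limit of 20 and 6.93 at 5, and CHGB by 7.44 and −1.03. NEFL changed by 10.56 at 20 and was not tested at 5. Members with a mean of 1 CPM or more over the primaries numbered 1 of 7 tested for Lung epithelium, 2 of 7 for Adipocyte, 2 of 7 for Schwann cell and 1 of 6 for Mast cell. They numbered 4 of 10 for Sympathetic neuron, 5 of 10 for Epithelium, 4 of 4 for Hepatocyte and 12 of 13 for Skeletal muscle. Members under that mean could pass 1 CPM in single primaries, such as FABP4 (up to 4.41 CPM) and CMA1 (up to 1.65 CPM). The most abundant members in the metastatic sections were SCGB1A1 at 176 CPM in dog 1 and FABP4 at 1042 CPM in dog 2. A difference between lesion types in the tumour cells themselves was not tested.

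The 29 genes that differ between T-cell-rich and other spots were weighed against regrouping, UMI totals and section edges. Chance is argued against, since 1 of 30 swaps of the classes within sections (the real one, 29 genes) gave as many genes and the highest of the others gave 18. Lower UMI totals as the whole cause are argued against: set against other spots matched on UMI total, the folds of the 29 genes were a median 0.919 of their own values (quartiles 0.758 and 1.05) and all 29 kept their sign, although 3 of them were still called among 7945 genes tested, with fewer spots. With spots thinned to 1000 UMIs the median was 0.553 (quartiles 0.254 and 0.911) and 4 of 29 turned their sign, so a part played by UMI depth stays open. Position at the section edge is argued against by a median of 0.978, with all 29 signs kept and 8 of the 29 still called; T cell and Macrophage scores went together across spots (mean partial rho 0.114, 11 of 11 sections), and whether this accounts for the 29 genes was not tested.

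The level of interferon response genes in the recurrent section was weighed against RNA from immune cells and against a few dominant genes. In the 471 recurrent spots lowest in T cell, Cytotoxic and Macrophage RNA, chosen in 1 random part of each spot's UMIs and measured in the other, that RNA stood at 0.438 of its level in all spots (95% bootstrap interval 0.416 to 0.460) and the interferon list at 0.841 (0.789 to 0.895). The interferon list stood at 2115 CPM there (1963 to 2263), against 416 CPM in the highest primary by the same choice of spots. The immune RNA of these recurrent spots still stood at 1130 CPM. It stood at 651 CPM in all spots of the primary of dog 9 and at up to 4467 CPM (dog 7) in those of the other primaries. The B cell, Plasma cell and Dendritic cell lists were not part of the choice. Without ISG15, MX1 and OAS2, which had the most counts, the recurrent section stood at 995 CPM and the highest primary at 277 CPM. These values argue against both as the whole cause; an interferon response of the recurrent lesion as a whole is a hypothesis that rests on 1 section.

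For the osteoclast-rich spots, 1 of 30 swaps of the classes within sections (the real one, 418 genes) gave as many genes and the highest of the others gave 0, which argues against chance labelling of the classes. These swaps also kept the chosen spots, so chance in their choice was not tested.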

How the results depend on the processing

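Alternatives added after seeing the data were the 2 limits on other-tissue UMIs, thinning to 4000 UMIs, leaving out edge spots and matching spots on UMI total. The limit of 5 other-tissue UMIs per 10000 came first. It left 26 of 1933 spots in the metastatic section of dog 2, and the limit of 20 was added once this was seen, before the fit at either limit had been looked at. A fit without mitochondrial genes, chosen before the data were examined, was not run, since no such gene is among the features. All results of the recurrent comparison moved by less than the spread between primaries under all its alternatives (138 values). Among named genes, 441 values of the metastatic comparison kept direction and side of the threshold, 127 kept direction only and 9 reversed. These counts were 109, 118 and 2 for the T-cell-rich and 556, 128 and 1 for the osteoclast-rich comparison. Of 20 Moran's I values of genes, 16 moved by more than the spread between sections with thinning, and 4 did not. The counts of T-cell-rich genes, osteoclast-rich genes and list pairs all fell with thinning. Unless stated, the cause of a change was not tested.

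Genes higher and lower in metastatic sections numbered 205 and 1. With the dog as a replicate block, which leaves 1 residual degree of freedom, 0 and 0 were called in edgeR (unadjusted p under 0.05 in 320 and 217), and 34 and 0 with the dog as a random block in limma-voom. The count of higher genes was 98 with spots thinned to at most 1000 UMIs, 64 with the recurrent section left out and 9 (with 0 lower) at the limit of 5. DESeq2 called 56 lower, and leaving out the primaries of dogs 1 and 2 gave 2 lower. At the limit of 20 the counts were 149 and 1, with 134 of the higher genes shared. Gene lists at the preset correlation numbered 10 higher and 4 lower at the limit of 5, and 15 and 4 at the limit of 20. Leaving out each section in turn gave 7 to 321 higher and 0 to 5 lower genes. Gene lists numbered 0 higher and 0 lower with an estimated correlation, 13 and 5 with the dog as a block (11 and 4 shared), and 9 to 10 higher and 2 to 5 lower with each metastatic section left out. Log2 changes turned to −1.03 for CHGB and −0.34 for PLIN1 at the limit of 5. Over left-out sections they ran from −0.90 to 12.72 for GAL, −1.15 to 9.44 for CHGB, −0.30 to 9.10 for SCGB1A1, −3.26 to 8.18 for CMA1, −4.99 to 8.30 for CIDEC, −0.18 to 10.05 for FABP4 and −0.40 to 5.81 for PLIN1, the negative ends coming with 1 of the metastatic sections left out.

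For T-cell-rich spots (19 higher, 10 lower), the counts were 71 and 71 with the top 5% of spots, 9 and 3 with the top 20%, 67 and 108 without neighbours, 4 and 0 with thinning to 1000 UMIs, 6 and 3 without edge spots, 9 and 0 with spots matched on UMI total, and 30 and 1 with RLE scaling. They were 254 and 1713 without the expression filter, which adds genes to the test, 31 higher with DESeq2, and 0 and 0 without the section as replicate block (unadjusted p under 0.05 in 18 and 9). Left-out sections gave 8 to 32 and 2 to 37. With thinning, RNASEH1 turned to 0.28 and SLC2A1 to 0.0207. The interaction (0 higher, 5 lower) gave 3 lower with the top 20%, and 0 to 46 higher and 2 to 63 lower with each metastatic section left out.

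For osteoclast-rich spots (224 higher, 194 lower), the counts were 438 and 363 without neighbours, 61 and 21 with thinning, and 0 and 0 without the section as replicate block (unadjusted p under 0.05 in 3 and 7), where SPP1 turned to −0.0182. Lower genes numbered 109 with the top 20%, 68 with RLE scaling, 2422 without the filter and 109 with DESeq2. Left-out sections gave 145 to 251 and 72 to 269.

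Correlated list pairs (14 positive, 1 negative) numbered 0 and 0 with thinning to 1000 UMIs, 7 positive with thinning to 4000, 2 negative with plain correlations, and 13 to 17 and 0 to 2 with sections left out. Relations of the T cell level (4) numbered 0 without the 2 farthest sections, which leaves 9, and 7 with the mean of log2 (CPM + 1), which left out B cell (adjusted p = 0.0832) and Cartilage (r = −0.342, adjusted p = 0.410).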

Other observations

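Primary tumours differed widely in cell type content, beyond the comparisons above. The Osteoclast list ran from 39.9 CPM in dog 4 to 26110 CPM in dog 8, and the Osteoblast list from 661 CPM in dog 3 to 63536 CPM in dog 8. The Cartilage list stood at 11674 CPM in dog 11 and at 134 to 589 CPM in the other 10 primaries. The Endothelial list stood at 6417 CPM in dog 7 and at 70.2 CPM in dog 3, and the Cytotoxic list ran from 3.85 CPM in dog 8 to 186 CPM in dog 3. The primary of dog 1 held 4454 CPM of the Skeletal muscle list, gathered in part of the section (Moran's I 0.835), while the other primaries held 4.82 to 150 CPM. The Erythroid list stayed between 0.494 and 6.99 CPM, without its haemoglobin members HBB and HBA, whose names were not among the features. The T cell list stayed between 18.3 CPM in dog 11 and 121 CPM in dog 7.

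In the metastatic section of dog 2 several lists were each gathered in parts of the section. Moran's I was 0.650 for the Sympathetic neuron list, 0.601 for the Adipocyte list, 0.579 for the Schwann cell list, 0.422 for the Epithelium list and 0.218 for the Mast cell list. The Hepatocyte list stood at 205 CPM there, with its most abundant member APOA1 at 215 CPM by scaled counts, and at 5.12 to 50.1 CPM in the primaries. The Sympathetic neuron list, added after the data had been seen, stood at 187 CPM, with PHOX2A at 54.0 and HAND2 at 32.8 CPM. In the metastatic section of dog 1 the Osteoclast list stood at 15492 CPM, above 10 of the 11 primaries.

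Lists that did not pass between metastatic and primary sections at the preset correlation were Neutrophil (adjusted p = 0.0844), Endothelial (0.0847), Cytotoxic (0.0928), Mural (0.127), Dendritic cell (0.128), Skeletal muscle (0.132), Osteoclast (0.414), Immediate early and heat shock (0.596) and Matrix (0.955). With the dog as a block, the Cytotoxic (0.000144) and Neutrophil (0.00940) lists passed as higher and the Skeletal muscle list (0.000167) as lower. That fit has 1 residual degree of freedom and the preset correlation, and without the block these 3 lists had adjusted p of 0.561, 0.358 and 0.703 with an estimated correlation. At the preset correlation, leaving out the metastatic section of dog 2 made the Osteoclast list higher (5.78e-06) and the Matrix list lower (0.0233), and leaving out that of dog 1 made the Mural (0.00171) and Endothelial (0.00892) lists higher. With both sections and an estimated correlation these 4 had adjusted p of 0.771, 0.978, 0.597 and 0.637. At the limit of 5 other-tissue UMIs per 10000 the Matrix list was higher instead (camera adjusted p = 5.54e-07), as was the Osteoclast list (0.00590). At the limit of 20 the Mural and Cytotoxic lists were higher (camera adjusted p = 0.0465 each). Both limits were fitted at the preset correlation only.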
